A study of Mus musculus with 4 samples.

How the data were processed

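Expression was measured in 4 samples of mouse THY1-enriched gonocytes, 2 cultured with vehicle and 2 with 100 nM RA, on Affymetrix Mouse Genome 430 2.0 arrays, 1 array per sample. Per the labels, 75 ng of total RNA per sample was amplified with the NuGEN Ovation system, version 2, and images were quantified with GCOS 1.2. The authors deposited 1 intensity per probe set and array on a linear scale. How probes were combined into these values and how the arrays were scaled is not given in the sources used here. The deposited intensities had equal trimmed means (125, with 2% trimmed at each end) on the 4 arrays, as a global scaling to 1 target gives, so they were used without further normalization. Amplification from small amounts of RNA starts near the 3' end of transcripts, which can lower the signal of probe sets far from it. Values near the background carry little information on ratios, and the pseudocount pulls their fold changes towards 0.

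Groups and replicate numbers came from the sample labels. After the 64 control probe sets were left out, 45037 remained. Each value was taken as log2(intensity + 5), where 5 is the 20th percentile of all values rounded to a whole number, so fold changes are on this scale and understate those of dim genes. A probe set was kept when its mean over the 4 arrays reached the 40th percentile of such means, which left 27022. RA was compared with vehicle with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over the probe sets kept. The fit had 2 residual degrees of freedom, to which the variance prior added 5.81. The fit had no term for the replicate number.

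Probe sets were named from the platform annotation, with symbols updated through Entrez IDs to a mouse gene table of assembly GRCm38.p6, which matched 34741 probe sets. One gene was named by 34945 probe sets, several by 932 and none by 9160, and probe sets with several genes named none here. A gene was represented by the brightest probe set that named it alone, by mean log2 value, which gave 18193 genes, 13011 of them above the filter. The annotation does not place the probes in a genome build, so no coordinates are given.

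Before the data were examined, 19 gene lists were fixed, 13 of germ cell states, retinoid biology and pathways and 6 of markers of other testis cells; some genes are on more than 1 list. List shifts were tested with camera (inter-gene correlation preset at 0.01, Benjamini-Hochberg over the lists), camera with an estimated correlation, and fry. Members were also adjusted over their list alone. The rule for named genes, fixed at the same time, took 13 genes whatever their test, then the 12 largest changes in each direction with an adjusted p under 0.05 and separated groups, filled up from those with an unadjusted p under 0.01, and per list up to 4 members past the threshold or the 2 with the smallest p. Further members are named as examples, chosen after their values were seen. List members with no probe set of their own are not analysed here.

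The same fit was tested on simulated arrays of 45037 probe sets with 2 against 2 samples and seeded changes. Over 5 runs it called 4.05% of the changes of log2 size 1, 72.6% of size 2, 97.7% of size 3 and 98.4% of size 4, each in the right direction, with 31 false calls beside 576 true ones. A seeded list, with every member raised by a log2 size of 1, was called in 5 of 5 runs and a random list in 0. The real lists held smaller and mixed changes, for which this gives no rate of detection. The simulated errors were independent between arrays and between probe sets, with no difference by replicate number. The real arrays need not meet this, so the rates and the list results may not hold for them. Alternatives planned before the data were examined covered the normalization (quantile, equal medians, cyclic loess), the pseudocount (1 and 20), the filter (none, and the 60th percentile), the variance model, the replicate number as a block, leaving out each array, probe set types, a 2-fold threshold, the mean of all probe sets of a gene, the list tests, and a 3-fold rule. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.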

Results

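Gonocytes, the male germ cells that resume development in the testis around birth, were taken from mice at 2 days post partum. They had been enriched by magnetic sorting for the surface protein THY1 and then kept for 8 h in a medium free of serum, growth factors and feeder cells. The medium held either ethanol, the vehicle, or 100 nM retinoic acid (RA), the vitamin A derivative that acts on nuclear receptors and is known to drive germ cells towards differentiation and meiosis. RNA from 2 vehicle and 2 RA samples was hybridised to 1 Affymetrix expression array each, so that 4 arrays with 45101 probe sets were compared. The mean signal with 2% trimmed at each end was 125 on each array. The median signals were 27.5 and 29.5 on the vehicle arrays and 26.6 and 26.9 on the RA arrays. The number of arrays limits the precision of every value. The labels do not say that the samples came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

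The comparison of RA with vehicle asked which transcripts in gonocytes respond to RA within 8 h. The largest differences were in Stra8 and in genes of retinoid metabolism and signalling, and 6 of the 12 largest higher values belonged to a fixed list of RA target genes. Stra8, which is needed for entry into meiosis, had signals of 188 and 53.3 on the vehicle arrays and of 783 and 1480 on the RA arrays, a 10.2-fold higher level with RA (log2 change 3.35 ± 0.53, SE, n = 2 per group). Cyp26a1, an enzyme that degrades RA, was 8.47-fold higher (log2 change 3.08 ± 0.41), and Rarb, an RA receptor, was 6.46-fold higher (2.69 ± 0.35). In the other direction Mcpt1, a mast cell protease, had the lowest ratio, with signals of 305 and 411 without RA and of 64.5 and 75.6 with it, a 4.8-fold lower level. No single probe set passed Benjamini-Hochberg adjustment in limma.

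Of 27022 probe sets above the signal filter, 0 were higher and 0 were lower at an adjusted p under 0.05 in limma, and the smallest adjusted p was 0.147. At an unadjusted p under 0.05 there were 743 probe sets, 296 higher and 447 lower, where chance gives 1351 if the arrays are independent. The split of the arrays by replicate number gave 4957. The fit had no term for that number, so this difference stayed in its residual spread. The count of 0 depended on the arrays used. It became 45 higher and 45 lower without RA replicate 1, 50 higher and 102 lower without RA replicate 2, and 1 higher without vehicle replicate 1, while no call was made without vehicle replicate 2. With 2 arrays against 2, an exact two-sided permutation test of a single gene cannot give a p below 0.33. Among 13011 genes, each read from its brightest probe set, both RA arrays lay above both vehicle arrays in 1841 and below them in 1642. These are 26.8% of the genes, where chance gives 33.3%. The 3 possible splits of the arrays share the genes between them. The split by replicate number took 51.9% and the remaining split 21.3%, so the share for treatment cannot be read against 33.3% alone. A gap of at least 2-fold between the groups was found in 30 genes, 23 higher and 7 lower with RA, and a gap of 3-fold in 10 genes, 9 higher and 1 lower. With 1 array left out, which makes a gap easier to reach, the 2-fold count lay between 55 genes, without vehicle replicate 2, and 131 genes, without vehicle replicate 1. It was 103 without RA replicate 1 and 120 without RA replicate 2.

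The 12 genes with the largest higher values among those with an unadjusted p under 0.01 and separated groups were Stra8, Cyp26a1, Rarb, Lrat, Tmem255a, Dhrs3, Ppbp, Stra6, Spon2, Crxos, Mbd1 and Nr0b1. Their log2 changes ran from 1.91 to 3.35, and none passed the threshold over all probe sets, with adjusted p between 0.147 and 1. Outside the target list, Tmem255a, which encodes a transmembrane protein, was 6.05-fold higher (log2 change 2.60 ± 0.35), and its other 2 probe sets above the filter gave 2.19 and 2.23. Mbd1, a protein that binds methylated CpG sites, went from signals of 214 and 220 to 814 and 897, a 3.88-fold difference with the smallest adjusted p, 0.147, shared with Mcpt1. The other 4 probe sets of Mbd1 gave log2 changes between 1.76 and 2.36. Ppbp, the precursor of a platelet chemokine, was 5-fold higher (log2 change 2.32 ± 0.52), with signals of 20.2 and 10.1 against 162 and 51.9. Spon2, an extracellular matrix protein, was 4.67-fold higher, from vehicle signals of 6.13 and 5.81, close to the pseudocount of 5. Crxos, a homeobox gene, was 4.06-fold higher. Nr0b1, an orphan nuclear receptor, was 3.75-fold higher. Leaving out 1 array moved the fold of some named genes by over 1.5 times. The log2 change of Stra8 was 4.21 without vehicle replicate 1 and 2.48 without vehicle replicate 2, and without RA replicates 1 and 2 in turn those of Cyp26a1 were 3.67 and 2.497, those of Lrat 3.48 and 1.72 and those of Ppbp 1.55 and 3.10.

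The 12 genes with the largest lower values by the same rule were Mcpt1, Slc35a4, Zbtb16, Slc6a4, Cbln2, Nptx1, Adpgk, Nefm, Sfrp4, Dpt, Snap25 and Tcl1, with log2 changes from −1.16 to −2.26. None of these passed the threshold over all probe sets either. The serotonin transporter gene Slc6a4 was 2.71-fold lower, the synaptic protein gene Cbln2 2.71-fold, the neuronal pentraxin gene Nptx1 2.61-fold, the neurofilament gene Nefm 2.38-fold and Snap25, a protein of synaptic vesicle fusion, 2.33-fold. A second probe set of Snap25 gave −1.34. Sfrp4, a secreted Wnt inhibitor, was 2.36-fold lower and Dpt, an extracellular matrix protein, 2.34-fold lower. For Slc35a4 and Adpgk the probe sets of 1 gene disagreed: −1.70 for the brightest of Slc35a4 against 0.22 and 0.15 for the other 2 above the filter, and −1.36 for the brightest of Adpgk against −0.02 for the other.

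**Figure D1:**
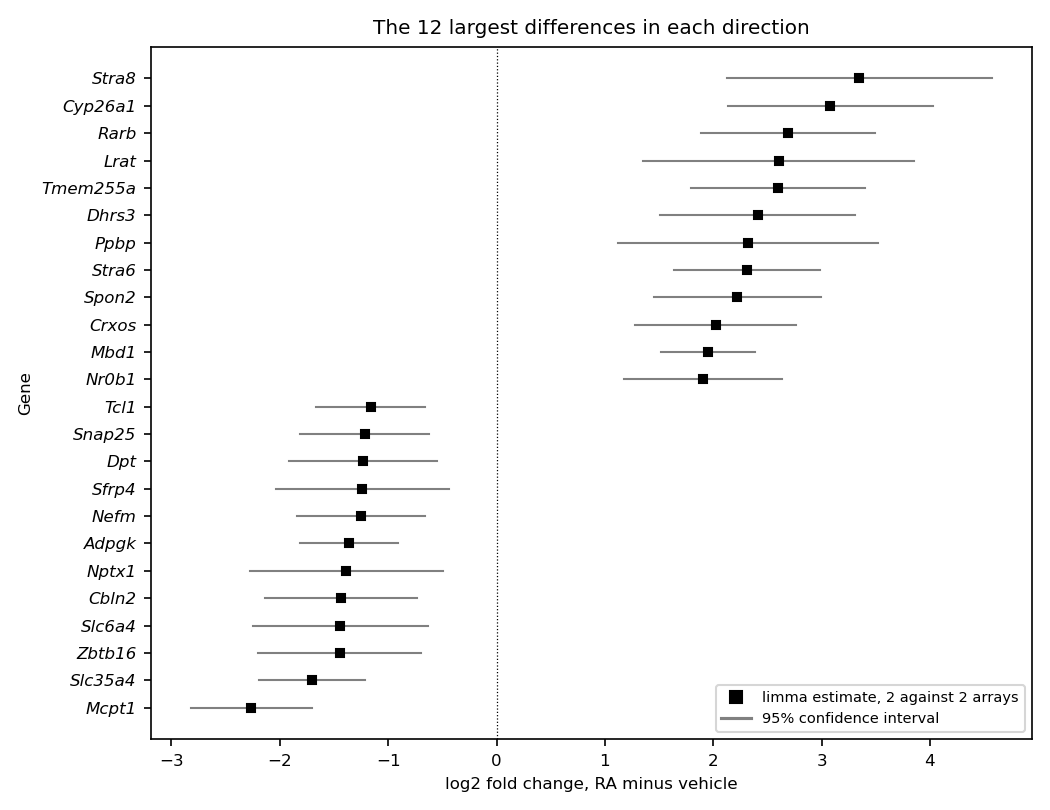
Log2 fold change of RA minus vehicle (x axis) for the 12 genes with the largest differences in each direction (y axis), among genes with an unadjusted p under 0.01 and separated groups. Squares are limma estimates from 2 against 2 arrays and lines are 95% confidence intervals; Stra8 is at 3.35 and Mcpt1 at −2.26, and none passed adjustment over all probe sets.

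The list of 30 RA target genes, fixed before the data were examined, had 25 members above the filter. Adjusted over the list alone, 8 of them rose, 1 fell and 16 did not pass, while over all probe sets 0 passed. Those that rose were Stra8, Cyp26a1, Rarb, Lrat, Dhrs3, Stra6, Rec8 and Cyp26b1. Dhrs3, which turns retinaldehyde back into retinol, had signals of 115 and 189 with vehicle and of 537 and 1210 with RA, 5.32-fold higher (limma, adjusted p = 0.00145 over the list alone). Stra6, a membrane receptor for the retinol-binding protein, rose 4.96-fold (limma, adjusted p = 0.000612 over the list alone). Lrat, which esterifies retinol for storage, rose 6.07-fold from signals of 8.73 and 5.54, close to the pseudocount of 5, to 34.7 and 130. Cyp26b1, a second RA-degrading enzyme, rose 2.53-fold and Rec8, a meiotic cohesin, 3.11-fold. Ret, the signalling receptor for the growth factor GDNF, was the member that fell, 2.01-fold, from signals of 514 and 562 to 254 and 277. Members that did not pass included Tgm2, a transglutaminase, with a log2 change of 0.80 ± 0.28, Nrip1, a nuclear receptor corepressor, with 0.49 ± 0.20, and Btg2, an antiproliferative factor, with −0.49 ± 0.22.

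The median log2 change of the RA target list was 0.44. Camera, which compares the mean test statistic of the members with that of the other genes and not the medians, called the list higher (camera, adjusted p = 8.95e-11 over 18 lists tested). With an estimated correlation the call was lost (adjusted p = 0.483 with an estimated correlation). Without its 9 members past the threshold, the list had a median of 0.0945 and was not called (camera, adjusted p = 0.0606). Those members were picked by their own p-values, so a weaker list was fixed in advance. The median was 0.245 without vehicle replicate 2 and 0.238 with the mean of all probe sets, with the call kept. The ratio of 3' to 5' signal, a sign of RNA and amplification quality, also differed between the groups for the control transcripts Actb and Gapdh. For Actb it was 1.72 and 1.73 with vehicle and 2.08 and 2.32 with RA. For Gapdh it was 1.56 and 1.47 with vehicle and 1.85 and 2.00 with RA. For the control transcripts Tfrc (log2 shift 0.178) and Pcx (−0.111) the groups overlapped. Camera called 7 lists in all, 5 higher and 2 lower, and with an estimated correlation 0 of them held.

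**Figure D2:**
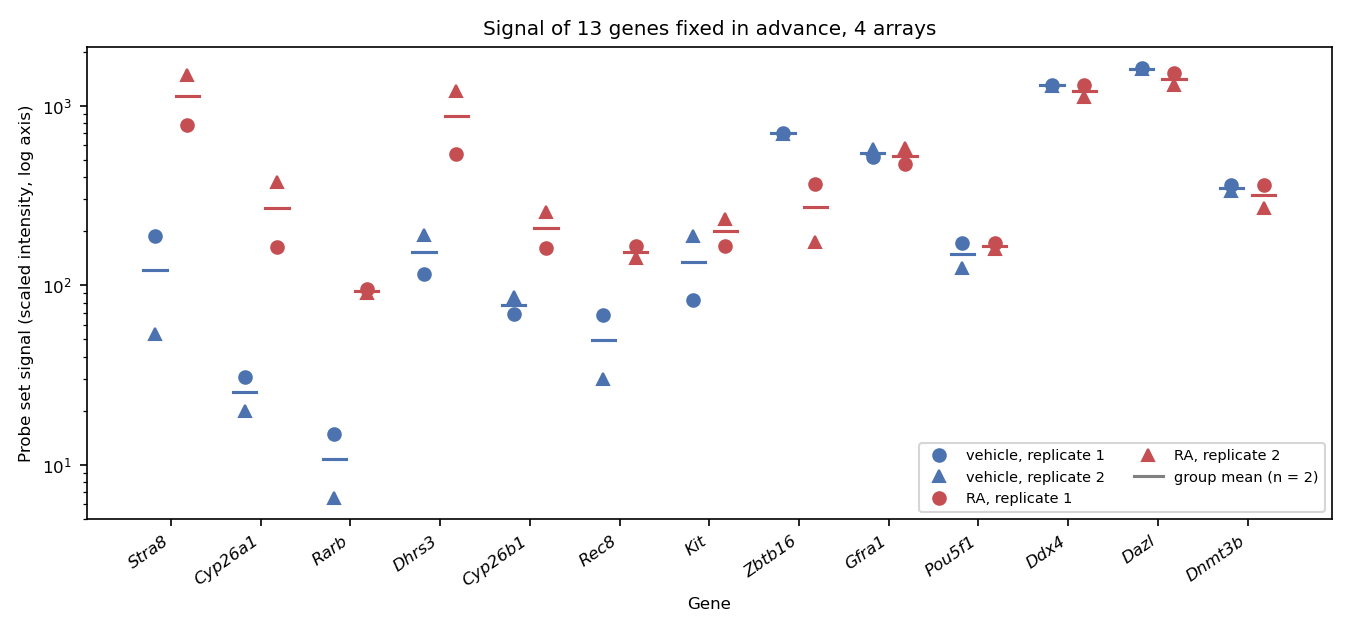
Probe set signal (scaled intensity, log y axis) of 13 genes chosen before the data were examined (x axis), 1 point per array, with circles for replicate 1, triangles for replicate 2 and a line at each group mean (n = 2). Stra8 reads 188 and 53.3 with vehicle and 783 and 1480 with RA, while Ddx4 reads between 1120 and 1310 on all 4 arrays.

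Genes of the undifferentiated spermatogonial state were lower as a group, as were general germ cell identity genes, with the same median of −0.14. Neither call held with an estimated correlation. The undifferentiated list had 26 members above the filter, 17 of them negative and 9 positive. Both RA arrays lay below both vehicle arrays in 8 and above them in 2. Adjusted over the list alone, 2 members fell and 24 did not pass. The median log2 change was −0.14 (camera, adjusted p = 0.00359, or 0.628 with an estimated correlation). Ret was the first and Zbtb16, a transcriptional repressor that maintains spermatogonial stem cells, the second: Zbtb16 went from signals of 701 and 699 to 368 and 174, 2.73-fold lower (limma, adjusted p = 0.0296 over the list alone), with −0.63 and −0.21 on its other 2 probe sets. Lhx1, a target of GDNF signalling, at −0.88 ± 0.23 and Id4, a stem cell marker, at −0.67 ± 0.20 were next in size of p and did not pass. Gfra1, the GDNF co-receptor, stood at −0.06 ± 0.20 on its brightest probe set and at −0.28 and −0.96 on the other 2, and Pou5f1, a pluripotency factor, at 0.16 ± 0.24. Without Ret and Zbtb16, picked by their own p-values, the median was −0.0931 and the list was not called (camera, adjusted p = 0.0606). Without vehicle replicate 1 it was 0.0253 and the call was lost, while with the call kept it was −0.281 without vehicle replicate 2 and −0.0636 with equal array medians. The 3' to 5' ratios of Actb and Gapdh were higher on both RA arrays here too, by 0.35 each on the log2 scale.

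Spermatogonial differentiation genes were not called as a list (12 members, median 0.0682, camera, adjusted p = 0.298), and without vehicle replicate 2 the median was −0.0938. Stra8 rose, and 11 did not pass, among them Kit, the receptor that marks differentiating spermatogonia, with signals of 83 and 188 against 165 and 234 (log2 change 0.63 ± 0.37), and Dnmt3b, a DNA methyltransferase, at −0.15 ± 0.22, with 0.22 on its other probe set. Of 26 meiosis genes, Stra8 and Rec8 rose and 24 did not pass; the median was 0.12 (camera, adjusted p = 0.0194; adjusted p = 0.656 with an estimated correlation). The synaptonemal complex genes Sycp1 at 0.07 ± 0.22 and Sycp3 at 0.02 ± 0.38 and the recombinase gene Dmc1 at −0.07 ± 0.26 did not pass. Without Stra8 and Rec8 the meiosis median was 0.0964 with no call, with the strict filter it was 0.0835 with no call, and with no call either it was −0.103 without vehicle replicate 2 and −0.0647 without RA replicate 1, while it was called at 0.294 without vehicle replicate 1, 0.297 without RA replicate 2 and 0.193 with equal array medians. Germ cell identity and transposon control genes were lower as a list (26 members, 23 of them negative, median −0.14, camera, adjusted p = 0.0171; adjusted p = 0.656 with an estimated correlation), yet 0 members passed. Ddx4, a germ cell RNA helicase, stood at −0.10 ± 0.21 and Dazl, an RNA-binding protein, at −0.20 ± 0.22. Without vehicle replicate 1 this median was 0.0113 and without RA replicate 2 it was 0.111, with no call in either case, and the strict filter also ended the call (median −0.12, camera, adjusted p = 0.0502). With the call kept, the median was −0.432 without vehicle replicate 2, −0.427 without RA replicate 1 and −0.0619 with equal array medians. The Actb and Gapdh 3' to 5' ratios were higher on both RA arrays by 0.35 on the log2 scale. Whether this bears on the meiosis and germ cell identity lists, which ran in opposite directions, was not tested.

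Stress genes were higher as lists with no member passing. Immediate early and heat shock genes had a median log2 change of 0.19 over 25 members, 22 of them positive (camera, adjusted p = 0.0059; adjusted p = 0.483 with an estimated correlation), with Myc at 0.44 ± 0.19 and the small heat shock gene Hspb1 at 0.35 ± 0.19. This call was lost without vehicle replicate 1 (median 0.135), and the median was 0.104 without RA replicate 1, 0.3 without vehicle replicate 2 and 0.127 with quantile normalization, with the call kept. Genes of the unfolded protein and amino acid response had a median of 0.19 over 20 members, 16 of them positive (camera, adjusted p = 0.0139; adjusted p = 0.483 with an estimated correlation). Herpud1, a factor of protein degradation at the endoplasmic reticulum, stood at 0.52 ± 0.21 and Xbp1, a transcription factor of that response, at 0.40 ± 0.20. The call was lost without vehicle replicate 1 (median 0.213) and without RA replicate 1 (median 0.272), and also with the strict filter (camera, adjusted p = 0.0502) and with the mean of all probe sets (camera, adjusted p = 0.0628). The Actb and Gapdh 3' to 5' ratios were higher on both RA arrays as well.

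The other 6 germ cell and pathway lists were not called in the main fit. Medians were 0.12 for 18 cholesterol synthesis genes (camera, adjusted p = 0.0531), with Lss and Mvd at 0.42 each (0.20 and −0.16 on the other 2 probe sets of Lss), and 0.0994 for 33 cell division genes (camera, adjusted p = 0.138), with the cyclin gene Ccne1 at 0.75 ± 0.39 (0.15 without vehicle replicate 2, 1.34 without vehicle replicate 1, and −0.01 on its other probe set) and the checkpoint kinase gene Bub1 at 0.38 ± 0.20. Cholesterol synthesis was called higher with equal array medians (camera, adjusted p = 0.0334), with no filter (0.0415), without vehicle replicate 2 (0.00509) and without RA replicate 1 (0.0377), and cell division without RA replicate 1 (0.0426). The cholesterol median was 0.229 without vehicle replicate 2, 0.192 with equal array medians, 0.0621 without vehicle replicate 1 and 0.0544 with the mean of all probe sets, and the cell division median was 0.0558 without vehicle replicate 2, 0.0471 without RA replicate 2 and 0.176 with equal array medians. They were 0.0725 for 26 genes of BMP, Nodal and activin signalling (camera, adjusted p = 0.235), with Id3 at 0.93 ± 0.31 and Smad3 at 0.47 ± 0.20, and 0.0436 for 25 Hox genes (camera, adjusted p = 0.298), with Hoxb4 at 0.94 ± 0.30 and Hoxb5 at 0.66 ± 0.27. The BMP list was called without RA replicate 2 (median 0.197, camera, adjusted p = 0.0384) and had a negative median without RA replicate 1 (−0.0154) and with the mean of all probe sets (−0.0388), and the Hox median was negative with the strict filter (−0.0521), without vehicle replicate 2 (−0.0861) and without RA replicate 1 (−0.188). Receptors, carriers and enzymes of retinoid synthesis had a median of −0.0451 over 19 members (camera, adjusted p = 0.343), which was 0.0316 with equal array medians, −0.119 without RA replicate 1, −0.0759 without RA replicate 2, −0.0261 without vehicle replicate 2 and −0.101 with the strict filter. Rdh10, which makes retinaldehyde, stood at 0.63 ± 0.20 and Ncoa2, a nuclear receptor coactivator, at −0.39 ± 0.22. Apoptosis and p53 target genes had a positive median, 0.0351, and a negative mean, −0.0218, and the test pointed down (21 members, camera, adjusted p = 0.633). Pmaip1 stood at −0.61 ± 0.26 and Ccng1 at −0.31 ± 0.24.

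**Figure D3:**
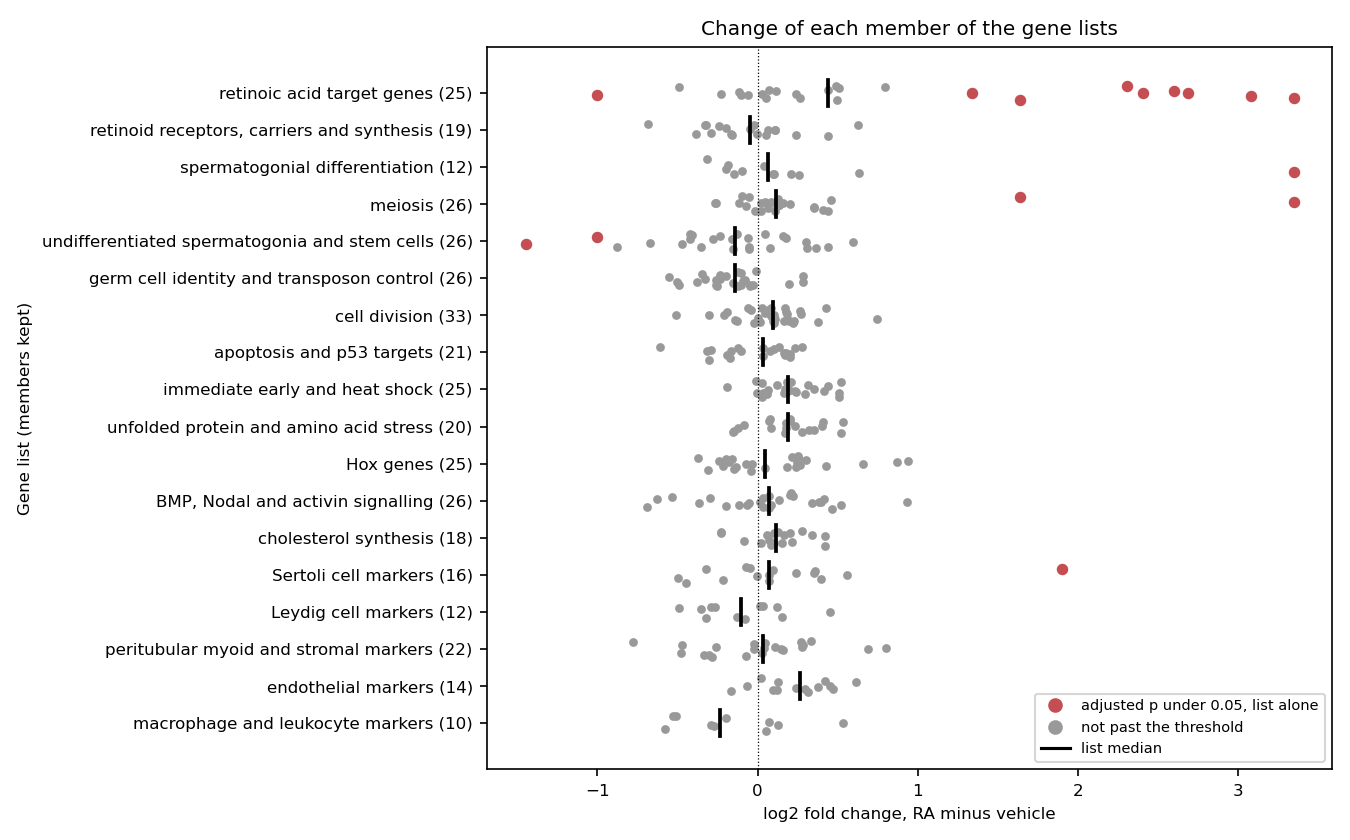
Log2 fold change of RA minus vehicle (x axis) for each member of the 18 lists tested (y axis, number of members above the filter in brackets). Red points passed an adjusted p of 0.05 over their list alone, grey points did not, and black bars are list medians, such as 0.44 for RA target genes and −0.14 for undifferentiated spermatogonia.

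Markers of other testis cells were read beside the germ cell lists, since a THY1 selection may carry them along. Endothelial markers were higher as a list, with a median log2 change of 0.27 over 14 members (camera, adjusted p = 0.0194; adjusted p = 0.483 with an estimated correlation), and 0 members passed. Tek, an angiopoietin receptor, stood at 0.62 ± 0.35 and Robo4, a guidance receptor of endothelium, at 0.45 ± 0.27. This call was lost without vehicle replicate 1 (median 0.312), without RA replicate 2 (median 0.0975) and with the strict filter (median 0.207, camera, adjusted p = 0.18). The Actb and Gapdh 3' to 5' ratios were higher on both RA arrays here as well. Sertoli cell markers had a median of 0.0719 over 16 members, 9 of them positive and 7 negative (camera, adjusted p = 0.167). Nr0b1 was the member that rose when adjusted over the list alone (limma, adjusted p = 0.00551). Among the other positive members, Wt1 and Sox9, transcription factors of Sertoli cells, stood at 0.56 ± 0.20 and 0.40 ± 0.19 and did not pass. The median was −0.10 for Leydig cell markers (12 members, camera, adjusted p = 0.343), with Fdx1 at 0.45 ± 0.22 and Vcam1 at −0.49 ± 0.25, and −0.23 for macrophage and leukocyte markers (10 members, camera, adjusted p = 0.298), with Fcgr3 at 0.54 ± 0.34 and C1qb at −0.51 ± 0.33. Calls for these markers turned with the arrays used. Leaving out 1 array makes the replicate numbers unequal between the groups, and these markers differ by number, so the turns can come from the number. Between arrays of number 1 and of number 2 in turn, medians were −0.14 and −0.215 for macrophage and leukocyte markers. They were 0.092 and −0.318 for Leydig markers and 0.0218 and −0.0582 for Sertoli markers. Leydig markers were called lower without vehicle replicate 1 (median −0.422, camera, adjusted p = 0.000119) and without RA replicate 2 (−0.288, 0.0498) and higher without vehicle replicate 2 (0.245, 0.00629). Macrophage and leukocyte markers were called lower without vehicle replicate 1 (−0.739, 1.54e-05) and without RA replicate 2 (−0.611, 0.000169) and higher without vehicle replicate 2 (0.34, 0.00509). Sertoli markers were called higher without vehicle replicate 2 (0.308, 0.000495) and without RA replicate 1 (0.236, 0.0375), with negative medians and no call without either of the other arrays. Peritubular and stromal markers had a median of 0.0334 while the test pointed down (22 members, camera, adjusted p = 0.696), and the median was −0.0773 with quantile and −0.0212 with cyclic loess normalization, with Igf1 at −0.78 ± 0.35 and Tcf21 at −0.47 ± 0.25. Of the red blood cell markers 1, Alas2, was above the filter, with a log2 change of −0.10 ± 0.37.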

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

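All tests in this part were chosen after the values they bear on had been seen. The control transcripts differed between the groups. The 3' to 5' signal ratio was higher on both RA arrays than on both vehicle arrays for Actb (shift 0.348 on the log2 scale) and for Gapdh (0.345). For Tfrc (0.178) and Pcx (−0.111) the groups overlapped.

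The 25 RA target genes above the filter had a median log2 change of 0.44 (SD 1.22) next to a largest control shift of 0.35, a comparison that decides nothing, since the members spread so widely, and the positions of the probes were not used, so the shift was left untested for the list. Whether the number of genes separated 2-fold exceeds chance cannot be judged from splits of 4 arrays, since the 3 possible splits cannot give a share under 0.05. The split by treatment gave 30 genes, the split by replicate number 104 and the remaining split, which crosses both, 1. Counting the treatment split itself, 2 of 3 splits gave at least as many. The split by replicate number called 157 probe sets in limma where the treatment called 0, which points to a structure of the samples. The remaining split also called 0, with 161 probe sets at an unadjusted p under 0.05 in limma against 743 for treatment. A response to RA, the difference the design names, remains the open biological explanation for the target genes, as a hypothesis.

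The fall of Ret and Zbtb16 within the undifferentiated list was set against 3 technical explanations. A smaller share of germ cells on the RA arrays would lower germ cell genes alike, but the germ cell identity list had a median of −0.14 (SD 0.21) against −1.0 for Ret, so such a loss does not account for the size of the fall. More Sertoli cells on the RA arrays would raise their markers together. The list's median was 0.0719, and 4 of 16 had both RA arrays above both vehicle arrays, beside 1841 of all 13011 genes. Sertoli markers were also higher by median on the arrays numbered 2 in both groups (0.42 and 0.305), with 9 of 16 higher in both and 5 lower in both. That difference can keep the count low even where the markers rise, so the count does not decide the question. The 3' to 5' shift was not decided, because the positions of the probes along the transcripts were not used here and the 5 probe sets of Ret and Zbtb16 above the filter (median −0.70, SD 0.46) are too few and too spread to set against the control shift of 0.35. An effect of RA is untested beyond the comparison itself.

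The brightest probe sets of Slc35a4 and Adpgk were 3.25-fold and 2.57-fold lower with RA. If the whole output of these genes fell, their other probe sets should follow, yet among the 3 others above the filter the largest log2 change was 0.22. The values argue against a fall of all transcripts of the gene. A change of a single transcript form, or a probe set that reads another transcript, may account for them and cannot be separated with the annotation used here.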

How the results depend on the processing

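Added after seeing the data were the block without the intensity trend and the lists without members past the threshold. Removing members by their own p-values weakens a list in advance, so a call lost in this way is no test of the list. Replicate numbers do not pair these samples by the labels. Leaving out 1 array makes the numbers unequal between the groups, so lists that differ by number can move for that reason. Deviations of same-numbered arrays correlated at 0.526 across probe sets, and the replicate block called 221 higher and 322 lower probe sets, or 160 and 231 without the trend, with 1 residual degree of freedom. Under the block the spermatogonial differentiation list passed in both forms (median 0.0682). No setting other than these and leaving out an array called a probe set. Leaving out an array, where the lone array of a group is assumed to vary like the other group, gave 0 to 50 higher and 0 to 102 lower calls, and 55 to 131 genes 2-fold apart (40 to 72 higher, 15 to 62 lower), because fewer arrays must then be separated. The 2-fold counts were 19 in all and 3 lower with a pseudocount of 20, 13 higher with the strict filter, and 10, 9 higher and 1 lower, at 3-fold. The RA target list kept its direction throughout (0.0945 to 0.516) and its call except with an estimated correlation or fry (0.439) and without called members (0.0945). Meiosis lost its call with the strict filter (0.0835), with both other tests (0.117) and without called members (0.0964), and the undifferentiated list with both tests (−0.14) and without called members (−0.0931). Over the arrays left out, medians ran from −0.103 to 0.297 for meiosis, −0.281 to 0.0253 for undifferentiated, −0.0938 to 0.124 for spermatogonial differentiation, −0.432 to 0.111 for germ cell identity, −0.145 to 0.0519 for apoptosis, −0.188 to 0.181 for Hox, −0.0154 to 0.197 for BMP, −0.15 to 0.308 for Sertoli, −0.422 to 0.245 for Leydig, −0.149 to 0.121 for stromal and −0.739 to 0.34 for macrophage lists, and log2 changes from −0.194 to 0.085 for Gfra1, −0.058 to 0.383 for Pou5f1, −0.21 to 0.003 for Ddx4, −0.355 to 0.058 for Dnmt3b and −0.459 to 0.258 for Alas2. Directions also turned with equal array medians (retinoid receptors 0.0316, Gfra1 0.022), with the strict filter (Hox −0.0521), with quantile (−0.0773) and cyclic loess (−0.0212) normalization for stromal markers, and with the mean of all probe sets (apoptosis −0.0552, BMP −0.0388, Sertoli −0.013, stromal −0.0788, Dnmt3b 0.038, Bub1 −0.033); the cause was not tested. Over all lists and alternatives 262 values kept direction and call, 26 turned, 27 lost a call and 14 gained one; for named genes 847 kept both, 10 turned and 96 gained a call. Genes near the background, such as Lrat and Spon2 with vehicle, have ratios set partly by the pseudocount.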

Other observations

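The tests in this part, other than that of the genes beside Mbd1, were chosen after the values had been seen. The next genes in size among those with an unadjusted p under 0.01 and separated groups, none past adjustment, included on the higher side Tmem119, a transmembrane protein known from osteoblasts and microglia (3.68-fold), Cidea, a lipid droplet protein (3.43-fold), Cyp7b1, an oxysterol hydroxylase (3-fold), Dmp1, a bone matrix protein (2.73-fold), and Itgb2, a leukocyte integrin (2.60-fold). On the lower side they included the secreted Wnt inhibitor Sfrp2 (2.12-fold), the mesenchymal transcription factor Foxf1 (2.07-fold), the ubiquitin ligase subunit Fbxo32 (2.07-fold) and the neuronal kinase Dclk1, with signals of 241 and 249 against 116 and 130 (1.96-fold). Signal from a neighbouring gene was weighed for Mbd1: among 4 probe sets of nearby genes above the filter, the highest log2 change was 0.53, for Cfap53, with 0.24 for Cxxc1, against 1.95 ± 0.19 for Mbd1, which argues against that explanation.

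Arrays with the number 2 had higher list medians of somatic cell markers than arrays with the number 1, whatever the treatment. Macrophage and leukocyte markers had a median log2 difference of 0.94 between the vehicle arrays and 0.997 between the RA arrays, with 10 of 10 genes higher on number 2 in both, such as Lyz2 with 426 and 857 with vehicle and 243 and 713 with RA. Leydig cell markers differed by 0.53 and 0.26, with the steroid enzyme gene Cyp11a1 at 700 and 1310 and at 660 and 1160, and Sertoli cell markers by 0.42 and 0.30. Of 12 Leydig markers, 8 were higher on number 2 in both groups and 0 lower in both. The Sertoli markers were mixed, with 9 of 16 higher in both and 5 lower in both, as were the stromal markers, with 14 of 22 higher and 5 lower. Germ cell identity genes differed by −0.46 and −0.51, with 21 of 26 lower on number 2 in both groups and 0 higher in both, and meiosis genes by −0.45 and −0.32. A candidate explanation is a different share of germ and somatic cells in the preparations. Set against 2000 random lists matched on signal, 3 of the 5 somatic marker lists lay above the central 95% in both groups (macrophage, Leydig and Sertoli) and the germ cell list below all random lists in both. Stromal markers (0.35 and 0.28) did so between the vehicle arrays, and endothelial markers (0.05 and 0.19) in neither group. These values go with a different share of germ and somatic cells. The somatic types did not move alike, which argues only against a dilution of germ cells by all of them in equal measure. The THY1 selection would remove cells without THY1, and the labels do not say whether a number marks a shared preparation. Thy1 itself read 329 and 168 on vehicle arrays 1 and 2, and 265 and 141 on RA arrays 1 and 2. Hybridisation spikes also differed by number: the bioB spike read 301 and 307 on the arrays numbered 1 and 455 and 627 on those numbered 2.

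The vehicle arrays differed in RA target genes as well. The list's median was 0.28 higher on vehicle 1 than on vehicle 2, with 15 of 25 genes higher. This lay at the 99.4th percentile of 10000 random lists, which had a median of 0.097 themselves (central 95% from −0.061 to 0.248). With 1 array on each side, such percentiles reflect a spread over genes and not over samples. Stra8 read 188 against 53.3 there, Rec8 68.6 against 30.0 and Rarb 14.9 against 6.56, while Dhrs3 read 115 against 189. More retinoid left in the cells of vehicle 1 is a possible explanation, as a hypothesis. Germ cell identity genes were 0.46 higher on vehicle 1 too, and several target genes are germ cell genes, so retained retinoid and a larger germ cell share cannot be told apart from the vehicle arrays. Between the RA arrays the target list was 0.17 higher on RA 2, at the 98.9th percentile of 2000 random lists, while the germ cell list was 0.51 lower there, so the lists ran apart in that group, where the response to the added RA differs as well.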
